A study of Mus musculus with 2 samples.

How the data were processed

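H3K27me3, the trimethylation of histone H3 lysine 27 laid down by the Polycomb repressive machinery, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in hindbrain dissected from mouse embryos at day 13.5. Per the labels, there were 2 biological replicates from pooled male and female embryos of strain B6NCrl, with fragments of 300 to 500 bp. Replicate 1 had 1 technical replicate and replicate 2 had 2, which were analysed together. The series has 1 group, so no condition was compared with another. The comparisons made were between replicates, between groups of genes and between parts of the genome. Control libraries were not analysed here.

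The authors deposited 4 peak lists in narrowPeak format on build mm10, per the file headers: 1 for each replicate, 1 for the pooled replicates, and a replicated list. Per the file headers, the pooled list was derived from both replicates' alignments, and the replicated list from the pooled list and both replicate lists. Replicate 1's list was derived from its alignment and 2 further files of unstated kind, and replicate 2's from its alignment and 1 of the same 2 files, per the file headers. The aligner, the peak caller, their versions and thresholds are not given in the sources used here. Each peak carries a fold enrichment over background, a ratio that the authors' peak caller assigned, and the -log10 of its p-value and q-value, as deposited by the authors. These are the authors' own values for each peak, and they were used only to describe, rank or filter peaks within a list. The smallest -log10 p in the replicate lists was 2.00 and 2.02, the smallest -log10 q 0.439 and 0.433, so the lists include weak peaks. Peak lists hold no read counts, so the depth of each library is unknown, and no interval or detection limit that needs depth is given. A gene without a peak was not called at the authors' threshold, which does not show that the mark was absent.

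Chromosome lengths of the mouse reference GRCm38.p6 matched the coordinates of the lists, and genes were taken from the GENCODE M21 annotation of that build. Chromosomes 1 to 19 and X were used, and no list held a peak on Y. Coordinates are given 1-based on mm10. A promoter was the 1 kb on either side of an annotated transcription start site (TSS), a window of 2001 bp. A protein-coding gene was called marked when a peak overlapped the window of at least 1 of its TSSs by 1 bp or more, and its coverage was that of its most covered window. Exons, introns and intergenic sequence were what remained after promoters, in that order. The CpG ratio of a promoter was the observed over the expected frequency of CpG in the window, and promoters of at least 0.6 were called CpG-rich. A gene was classed by the highest ratio over its TSSs, which need not be at its most covered window. Broad domains were peaks joined across gaps of up to 3 kb that reached at least 10 kb.

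Peak lists were compared by the share of peaks with at least 50% of their length covered by the other list and by the Jaccard index, the base pairs common to both lists divided by those covered by either. Both were set against 1000 circular shifts of 1 list along each chromosome in a one-sided permutation test, whose smallest possible p is 0.001. The same shifts tested the genomic features, with Benjamini-Hochberg adjustment over the 4 features. A circular shift keeps the spacing of the peaks but ignores gaps in the assembly and mappability. Gene lists were tested by two-sided Fisher's exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 23 lists. Each list was also set against 10000 random lists matched on promoter CpG ratio and gene length. The 18 gene lists, covering Hox genes, brain regions, other germ layers, signalling, imprinting, the Polycomb machinery, cell cycle inhibitors and housekeeping genes, were fixed from general knowledge, together with 5 gene families taken by symbol. Genes are not replicates, and neighbours can share a domain, so these p-values describe the present libraries and not a population of embryos. All listed symbols matched the annotation. The test of the X-linked genes in the closing section used 6 genes known to escape X inactivation and 24 ubiquitously expressed genes.

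The genes named were set by a rule. It took all Hox genes, summarised by cluster and paralog group. From each list it took up to 4 marked genes with the most replicated-peak base pairs within 5 kb of a TSS and up to 3 unmarked genes with the least. It added the 15 genes outside the Hox clusters with the most base pairs within 10 kb and the genes in the 10 longest domains. The lists, this rule, the tests and the alternatives were fixed before the data were examined, except the restriction to autosomes and the tests of the X chromosome, which were chosen afterwards. Errors are SDs over the 2 replicates. The alternatives were stricter thresholds of -log10 q of at least 2 and fold enrichment of at least 3, other overlaps, windows, gaps and backgrounds, ranking peaks by width in place of fold, the pooled list, and each replicate's own list in place of the replicated one.

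Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Interval arithmetic was tested on simulated intervals against bedtools 2.31.1, with 0 differences. For the overlap of replicate peak sets, the shift test was tested on simulated sets of 200 intervals. It called 7% of 100 unrelated pairs and 100% of 100 pairs that shared 30% of their intervals. These intervals were placed uniformly on a single short chromosome, without clustering or assembly gaps. The shares therefore do not show the test's error on the peak lists. For the gene lists, simulated lists of 25 genes were drawn from the 21670 genes. Lists drawn with 4 times the odds of being marked were called in 76% of 100 draws and random lists in 4%. The adjustment there ran over simulated lists and not over the reported ones, which held 7 to 1134 genes. These shares therefore do not show how often the reported tests would call a list.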

Results

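H3K27me3 was profiled in hindbrain of mouse embryos at day 13.5 in 2 biological replicates, each a pool of male and female embryos. At this stage the hindbrain holds dividing progenitors and newly born neurons of the cerebellum, pons and medulla. The replicates' lists held 116517 and 109417 peaks, which covered 53.4 and 52.7 Mb (53.0 ± 0.437 Mb, SD, n = 2). This was 1.96% and 1.94% of the length of all chromosomes with Y included, although no peak lay on Y. The authors' replicated list, used below for the main values, held 64356 peaks over 56.5 Mb with a median width of 510 bp. Read depth is unknown, since peak lists carry no counts.

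The question of which genes carried the mark was addressed at promoters. Of 21670 protein-coding genes, 5038 (23.2%) had a replicated peak within 1 kb of a TSS. Outside the Hox clusters, the genes with every base pair within 10 kb of a TSS covered were Cdx2 (chromosome 5, 147300805 to 147307270), a gut regulator, Nkx6-2, a homeobox gene of ventral neural progenitors, Prdm12, a regulator of sensory neurons, and the T-box genes Tbx2, Tbx3 and Tbx5 of heart and limb. The list continued with the oligodendrocyte regulators Olig1 and Olig2, the motor neuron gene Mnx1, Dbx1 of ventral interneuron progenitors, Gata2 of neurons and blood, and Nr2e1, a neural stem cell regulator that shared its window with its neighbour Ostm1. Gm4881 and Pax7, a dorsal patterning gene, completed it. Promoter windows of 10 of these 15 genes were also fully covered in both replicates. Those of Prdm12, Tbx5, Dbx1, Pax7 and Tbx2 lacked part of their 2001 bp in at least 1 replicate, and Tbx2 was lowest at 1654 and 1846 bp.

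In the replicates' own lists, 5500 and 5410 promoters were marked (25.2 ± 0.294%, SD, n = 2), and 4641 were marked in both. Of the promoters marked by replicated peaks, 4497 (89.3%) were marked in both replicates and 57 in neither. The count depended on the coverage asked for, since 2923 genes had at least 50% of a window covered.

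Transcription factors that specify brain regions were mostly marked, in the forebrain and midbrain list as in the hindbrain and cerebellar list. Expression was not measured, so these shares do not show whether the marked genes were active in the tissue. All 25 forebrain and midbrain transcription factors were marked (adjusted p = 6.35e-16, Fisher's exact test against the 23.2% of other genes), among them Dlx1 and Lhx6 of forebrain interneurons, Fezf2 of cortical projection neurons and Rax of the eye field. Of 36 hindbrain and cerebellar transcription factors, 34 were marked (94.4%, adjusted p = 5.73e-19, Fisher's exact test). These included the proneural gene Neurog1, Egr2, a regulator of hindbrain segments, Gata2 and Pax7, each with 2001 bp of its window covered. The 2 unmarked members, Meis1 and Meis2, encode cofactors of Hox proteins and had 0 bp in their windows in both replicates.

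Genes of neurotransmitter identity and glia were marked more often than other genes, and broadly expressed neural genes did not pass the test except among genes with CpG-rich promoters. Of 20 neurotransmitter genes, 16 were marked (80%, replicates 85 ± 7.07%, SD, n = 2, adjusted p = 2.29e-07, Fisher's exact test). Chat and Slc18a3, which make and package acetylcholine and share a locus on chromosome 14, the glycine transporter gene Slc6a5 and the vesicular GABA and glycine transporter gene Slc32a1 were covered over 1867 to 2001 bp. Tph2 and Ddc, which act in serotonin synthesis, had 0 bp, and Dbh of noradrenaline synthesis had 0 bp in the replicated list and 203 bp in replicate 1. Of 18 glial genes, 11 were marked (61.1%, adjusted p = 9.83e-04, Fisher's exact test). Olig1 and Olig2 were covered in full, the oligodendrocyte precursor receptor gene Pdgfra over 1829 bp and the astrocyte filament gene Gfap over 2001 bp, while the myelin gene Mog had 0 bp in both replicates. The myelin gene Mag had 0 bp in the replicated list and 202 bp in replicate 1, and the astrocyte water channel gene Aqp4 0 bp and 221 bp in replicate 2.

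Of 25 pan-neural progenitor and neuron genes, 9 were marked (36.0%, adjusted p = 0.185, Fisher's exact test). Among genes with a CpG ratio of at least 0.6 the list passed at 56.2% (9 of 16, adjusted p = 0.0122, exact test). The share was 20% with coverage of at least 50% or a fold enrichment of at least 3. The marked members were led by the progenitor transcription factor genes Sox1 (2001 bp), Hes1 (1332 bp), Sox2 (1736 bp) and Sox3 (665 bp). Elavl4, a neuronal RNA-binding protein gene, and Fabp7 of radial glia had 0 bp in both replicates, and the X-linked neuroblast gene Dcx had 0 bp in replicate 1 and 296 bp in replicate 2.

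Regulators of other germ layers and signalling ligands were also marked. Of 34 mesoderm and muscle transcription factors, 30 were marked (88.2%, adjusted p = 5.93e-15, Fisher's exact test), including T (Brachyury) of early mesoderm, Tbx2, Tbx15 and the hindlimb gene Pitx1. Unmarked were the muscle regulators Myog, Myf5 and Myf6, each with 0 bp in the replicated list, although 240 bp near Myf5 was called in replicate 1 and 219 bp near Myf6 in replicate 2. Of 18 endoderm and gut transcription factors, 16 were marked (88.9%, adjusted p = 1.54e-08, exact test), with Barx1, Cdx2, Foxa1 and Foxa2 covered in full. The unmarked Hnf4g and Isx, both of intestine, had 0 bp in both replicates. Of 22 neural crest, meninges and skeletal genes, 20 were marked (90.9%, adjusted p = 8.34e-11, exact test), among them Msx2, Tfap2a, Foxc2 and Alx4, and the extracellular matrix genes Dcn and Lum were not. All 36 signalling ligand genes were marked (adjusted p = 1.08e-22, exact test), with Wnt10b covered in every one of the 10001 bp around a TSS in both replicates, followed by Fgf8, Wnt10a and Wnt11.

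Marker genes of vessels, blood and microglia did not pass the test, with 8 of 22 marked (36.4%, adjusted p = 0.233, Fisher's exact test). With at least 50% of the window covered the list passed at 31.8% (adjusted p = 0.0277, exact test). With CpG-rich genes only, just 2 genes were left, both marked (100%, adjusted p = 0.0806, exact test). The blood regulator Tal1 and the vessel genes Flt1 and Erg were among the marked, with 2001, 2001 and 1922 bp, as was the pericyte channel gene Kcnj8 with 1906 bp. The microglial receptor gene Csf1r and the endothelial cadherin gene Cdh5 had 0 bp in both replicates, and the microglial gene Aif1 0 bp in the replicated list and 506 bp in replicate 1. Of 18 pluripotency and germline genes, 6 were marked (33.3%, adjusted p = 0.437, exact test). With CpG-rich genes only, 1 of the 5 genes left was marked (20%), a share below other genes. Pou5f1 and Prdm1 were covered in full, Prdm14 over 1842 bp and Lin28a over 1508 bp. The germ cell genes Dazl, Ddx4 and Dppa3 had 0 bp in the replicated list, but Ddx4 had 334 bp in replicate 1 and 239 bp in replicate 2.

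Of 28 imprinted genes, 12 were marked (42.9%, adjusted p = 0.0325, Fisher's exact test), with the growth factor gene Igf2, the growth regulator Grb10, Rasgrf1 and the placental regulator Ascl2 covered in full. Cd81, Impact and Magel2 had 0 bp in both replicates. This call was lost in a permutation test against random lists matched on CpG ratio and length (adjusted p = 0.0801) and, by exact tests, in replicate 2's own list (adjusted p = 0.0619, against 0.0111 in replicate 1), with windows of 500 bp or 2.5 kb (0.0626 and 0.0825) and with a -log10 q of at least 2 (0.0872). Over all alternatives the adjusted p ranged from 0.00389 to 0.0872. Of 24 genes of the Polycomb machinery, 6 were marked (25%, adjusted p = 0.811, Fisher's exact test). The share lay below that of other genes in replicate 1's own list (25%, against 25.4% of all genes) and under 5 other alternatives, without passing the test, and was lowest at 12.5% with coverage of at least 50%. Bmi1 and Phf19 had 2001 and 1945 bp covered, Cbx4 502 bp, and Cbx8 395 bp but 0 bp in replicate 1, while Ezh2, the H3K27 methyltransferase, its partner Eed and Cbx6 had 0 bp.

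Of 7 cell cycle inhibitor genes, 4 were marked (57.1%, adjusted p = 0.0709, Fisher's exact test). Cdkn2a and Cdkn2b, neighbours on chromosome 4, were covered in full, Cdkn2c over 1564 bp and Cdkn1a over 1289 bp, and Cdkn1b, Cdkn1c and Cdkn2d were unmarked. In each replicate's own list 5 of the 7 were marked, with Cdkn1c added at 200 and 184 bp, and exact tests gave adjusted p = 0.0198 in replicate 1 and 0.0184 in replicate 2. Over all alternatives the adjusted p ranged from 0.00544 to 0.173. Of 28 housekeeping genes, 2 were marked (7.14%, adjusted p = 0.0589, exact test), B2m over 144 bp and Reep5 over 312 bp. Actb, Eef1a1 and Chmp2a had 0 bp in both replicates. Replicate 1's list alone passed the exact test for fewer marked housekeeping genes (adjusted p = 0.0353) and replicate 2's did not (adjusted p = 0.148), with a range of 0.0316 to 0.148 over all alternatives.

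Olfactory receptor, vomeronasal receptor and Zfp genes were marked less often than other genes. Of 1134 olfactory receptor genes, 10 were marked (0.882%, adjusted p = 1.97e-114, Fisher's exact test), led by Olfr94, Olfr95, Olfr222 and Olfr63. The replicates' own lists marked 20 and 23 of them (1.76% and 2.03%) and the pooled list 2.91%. Of 331 vomeronasal receptor genes, 0 were marked (adjusted p = 8.21e-38, exact test), a call lost with CpG-rich genes only, where 1 gene was left. Of 397 Zfp genes, named for zinc finger proteins, 35 were marked (8.82%, adjusted p = 1.54e-13, exact test), with Zfp853 and Zfp296 covered in full. Their share was 16.9% with windows of 2.5 kb and 3.02% with coverage of at least 50%, and the call held. Of 57 clustered protocadherin genes, 11 were marked (19.3%, adjusted p = 0.558, exact test), with Pcdhgb7 covered over 1337 bp. With a fold enrichment of at least 3 the list passed as less marked at 7.02% (adjusted p = 0.0457, exact test). The share was also 7.02% with coverage of at least 50% and 0% with neighbours counted once, both without a call. The latter setting marks a unit only if at least 50% of its members are marked, so it bears little on this family. With CpG-rich genes only, the share lay above other genes at 26.7% (4 of 15). Of 57 keratin-associated protein genes, Krtap17-1 and Krtap5-4 were marked (3.51%, adjusted p = 1.67e-04, exact test). The share was 12.3% in replicate 1, 7.02% in replicate 2 and 14% in the pooled list. The call was lost in a permutation test against matched random lists (adjusted p = 0.103) and with neighbours within 100 kb counted once (0%, adjusted p = 0.164, exact test). That last setting marks a unit only if at least 50% of its members are marked. Over all alternatives the adjusted p ranged from 1.16e-05 to 0.164. Against random lists matched on CpG ratio and length, 11 lists were more marked and 4 less marked, and 12 and 4 were by Fisher's exact test. The 4 lists differed, since keratin-associated protein genes dropped out and housekeeping genes came in (adjusted p = 0.0319, permutation test).

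**Figure D1:**
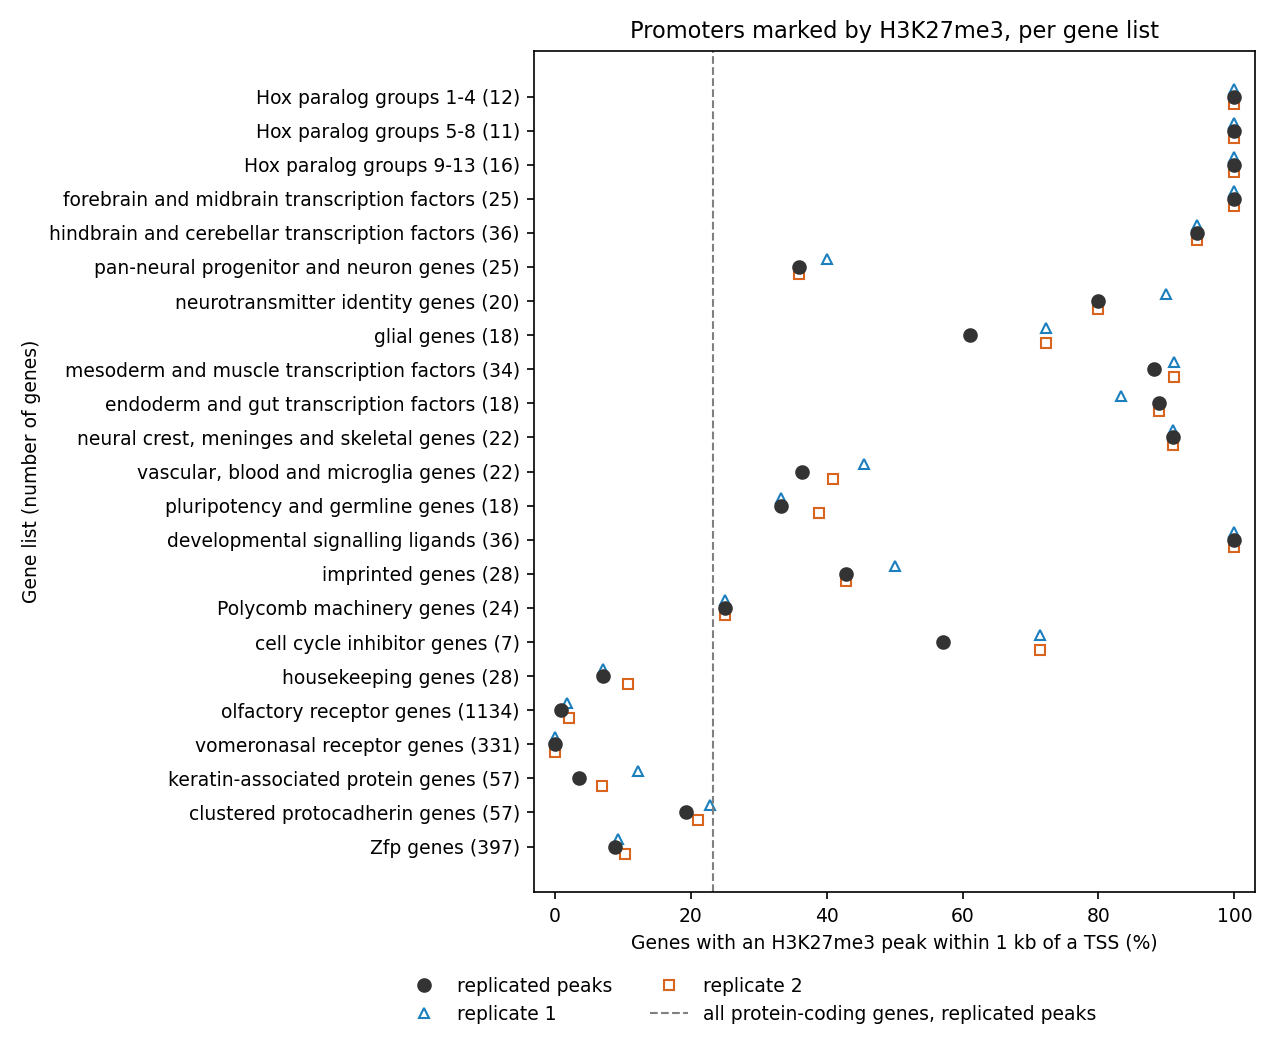
Percent of genes in each list with a peak within 1 kb of a TSS (x axis), for the replicated list (filled circles), replicate 1 (triangles) and replicate 2 (squares), with the number of genes in brackets and a dashed line at the 23.2% of all protein-coding genes. The forebrain and midbrain, ligand and Hox lists sit at 100% in every list of peaks, and the olfactory receptors at 0.882% in the replicated list.

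All 39 Hox genes, which assign position along the head-to-tail axis, were marked in the replicated list and in each replicate's own list. Fisher's exact tests gave adjusted p = 5.16e-08, 2.04e-07 and 1.83e-10 for paralog groups 1 to 4, 5 to 8 and 9 to 13. These tests count neighbours of a cluster singly, and with neighbours within 100 kb counted once, adjusted p was 0.00477 for each set (exact tests). In that setting only the listed genes were joined into units, and all other genes were still counted singly. The sets also draw on the same Hox clusters, so their tests are not independent. Mean coverage of gene bodies was lowest in paralog groups 1 to 4, at 84.7% (74.1 ± 5.98% in the replicates, SD, n = 2). This mean was 98.1% (92.5 ± 0.443%) in groups 5 to 8 and 98.6% (96.5 ± 0.760%) in groups 9 to 13. Some annotated bodies contain genes of another set, as Hoxa3 does Hoxa5 and Hoxa6, and Hoxc5 does Hoxc9. The sets were therefore not measured on separate sequence. Mean coverage of the promoter window was also lowest in groups 1 to 4, at 85.4% against 96.3% and 100% in the replicated list. By median coverage of the window, groups 1 to 4 were not lowest in that list, at 100% against 96.7% in groups 5 to 8 and 100% in groups 9 to 13. The median order was the same in replicate 2 (98.4% against 91.1% and 100%). In replicate 1 groups 1 to 4 had the lowest median (87.6% against 88.3% and 100%). Within paralog groups 1 to 4, genes differed. Hoxa2 was the least covered, with 15.9% of its body in the replicated list and 16.2% and 21.1% in the replicates, followed by Hoxb2 with 69.2%, 19.5% and 48.0%. Hoxa1 had 49.9% of its promoter window covered but 91.6% of its body, and Hoxb1 100% of both.

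The HoxC cluster (chromosome 15, 102921103 to 103036852) was 98.6% covered, HoxD (chromosome 2, 74668310 to 74765142) 92.3%, HoxA (chromosome 6, 52155590 to 52260880) 85.3% and HoxB (chromosome 11, 96194316 to 96368256) 84.2%. The replicates gave 96.8 ± 0.853%, 87.4 ± 3.12%, 79.7 ± 2.20% and 76.9 ± 2.53% in the same order. By promoter window in the replicated list, the least covered gene was Hoxa2 in HoxA (19.2%), Hoxb2 in HoxB (81.1%, with 34.0% and 72.2% in the replicates) and Hoxc8 in HoxC (91.3%), and in HoxD every window was covered in full. These ranks did not all hold in the replicates. Hoxb4 was lower than Hoxb2 in replicate 2 (64.0%), and Hoxc8 was not the lowest of HoxC in either replicate. Neighbouring genes share peaks, so no test between genes or paralog groups was made.

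**Figure D2:**
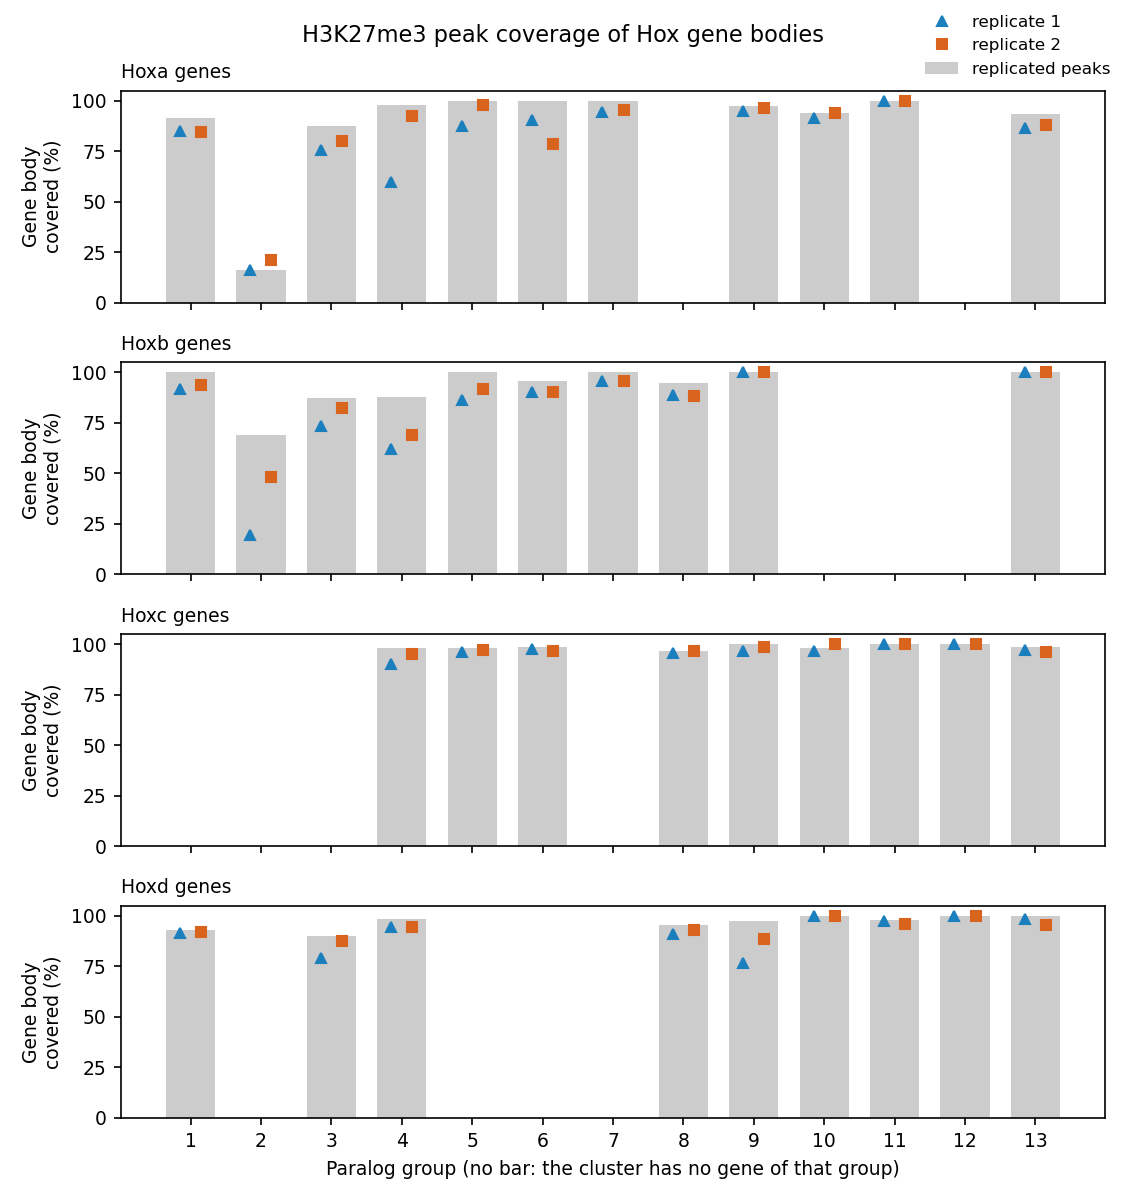
Percent of each Hox gene's body covered by peaks (y axis) by paralog group (x axis) in the 4 clusters, for the replicated list (grey bars), replicate 1 (triangles) and replicate 2 (squares). Hoxa2 is lowest at 15.9%, and in groups 9 to 13 the lowest bar is Hoxa13 at 93.4%.

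Peaks joined across gaps of up to 3 kb formed 2034 domains of at least 10 kb, which spanned 46.4 Mb with a median of 16.1 kb and held TSSs of 1347 protein-coding genes. The longest, 395 kb on chromosome 8 (11955874 to 12350870), held A230072I06Rik and ended 44.4 kb from Sox1. Next came 253 kb on chromosome 4 with Prdm16, a regulator of neural stem cells and brown fat, and Actrt2. A domain of 248 kb on X followed, with the cohesin gene Smc1a, Iqsec2, Hsd17b10 and Ribc1, and then 202 kb over Casz1, a zinc finger gene. The HoxC cluster lay in a domain of 196 kb, Olig2 with 4932438H23Rik in 169 kb, and most of HoxA with Evx1, Gm28308 and 5730596B20Rik in another 169 kb. The remaining 3 of the 10 longest were 172 kb on X with Apoo, Klhl15 and Fam90a1b, 166 kb around Hes1 and 163 kb with Dbx1 and Htatip2.

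The replicates gave 2505 and 2411 domains (2458 ± 66.5, SD, n = 2), and 1735 and 1815 of the replicated domains were at least 50% covered by a domain of replicate 1 and 2. In the domain with Smc1a, peaks covered 50.7% of the length in replicate 1 and 76.4% in replicate 2, and in the other X domain among the 10 longest, with Apoo, 35.3% and 59.4%. The number depended on the joining rule and the list, at 1059 with gaps of up to 1 kb, 1014 with a fold enrichment of at least 3 and 3836 in the pooled list.

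Promoters held 12.7% of the replicated base pairs (12 ± 0.406% in the replicates, SD, n = 2), 4.94 times the mean of 2.57% over shifted positions. Exons held 6.29% (6.16 ± 0.0454%), 2.02 times the mean of 3.12%. Both were above all 1000 shifts (adjusted p = 0.002, one-sided permutation test, the smallest possible). Introns held 32.7% against 34.9% on average and intergenic sequence 48.3% against 59.4%, with 31 and 0 of the 1000 shifts as low.

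Genes with a CpG-rich promoter were marked slightly more often than others in the replicated list, at 24.8% of 8221 against 22.3% of 13449 (odds ratio 1.15, p = 3.42e-05, two-sided Fisher's exact test). CpG-rich promoters are typical of developmental and housekeeping genes, but the cutoff left many marked developmental genes among the others. Only 21 of the 36 ligand genes and 4 of the 12 Hox genes of paralog groups 1 to 4 reached it, and all genes of both lists were marked. By the same exact test, the difference did not pass in replicate 1 (odds ratio 0.993, p = 0.847) or replicate 2 (odds ratio 1.04, p = 0.251) on its own, in the pooled list (0.953, p = 0.124) or with the outermost TSS of each gene only (1.01, p = 0.833). Over all alternatives the odds ratio ranged from 0.953 to 1.36 and p from 1.37e-17 to 0.847, so the association was not stable across these lists.

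The X chromosome stood apart between the replicates. Peaks covered 13.3 kb per Mb of X in replicate 1 and 33.8 in replicate 2, a ratio of 2.54, whereas the 19 autosomes had ratios from 0.886 to 0.948 (mean 0.920 ± 0.0179, SD over autosomes). X held 6703 peaks in replicate 1 and 14464 in replicate 2, and 159 (16.8%) and 258 (27.2%) of its 948 protein-coding promoters were marked. On autosomes the marked shares were 25.8% and 24.9%. Of the broad domains in the replicates' own lists, 160 and 361 lay on X. Among autosomes, coverage was highest on chromosomes 19 (34.9 ± 1.71 kb per Mb, SD, n = 2) and 11 (31.6 ± 1.81) and lowest on 3 (10.7 ± 0.634). The ratio for X was 2.25 with a -log10 q of at least 2 and 2.76 with a fold enrichment of at least 3, above every autosome in both cases. With 1 value per replicate this difference has no test.

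**Figure D3:**
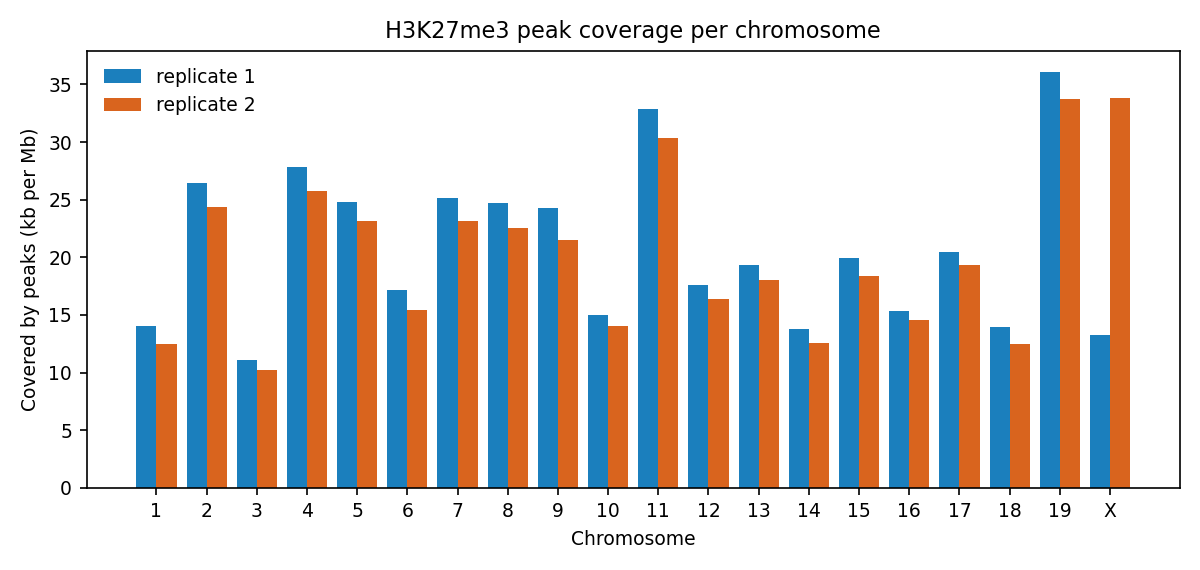
Kilobases covered by peaks per Mb of each chromosome (y axis) in replicate 1 (blue bars) and replicate 2 (orange bars). On each of the 19 autosomes replicate 1 is slightly higher, with ratios of 0.886 to 0.948, and on X replicate 2 is 2.54 times higher.

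The replicates shared peaks far more often than shifted positions did. Of replicate 1's peaks, 39.4% had at least 50% of their length covered in replicate 2, against a mean of 2.08% and a highest value of 3.72% over 1000 shifts. Of replicate 2's peaks, 40.5% were covered in replicate 1, against 2.04% and 3.26% (p = 0.001 for both, one-sided permutation test, the smallest possible). By base pairs, 31.1 Mb was common, or 58.3% and 59.0% of the replicates' coverage, with a Jaccard index of 0.415. On autosomes alone the shared shares were 37.5% and 43.7%.

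Sharing was more frequent among peaks of high fold enrichment, the value that the authors' caller gave, and as much so among wide peaks. Among the 25% of peaks with the highest fold in each list, 73.2% of replicate 1's peaks and 71.3% of replicate 2's were at least 50% covered by the other replicate (72.3 ± 1.35%, SD, n = 2). Among the 25% with the lowest fold these were 21.2% and 25.7% (23.5 ± 3.15%). The intervals between gave 36.8% and 26.2% in replicate 1 and 37.0% and 28.0% in replicate 2. The mean difference between the highest and lowest 25% was 48.8 percentage points by fold and 50.2 by width. Peaks were not ranked by fold among peaks of like width, so the part of fold was not separated from that of width.

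**Figure D4:**
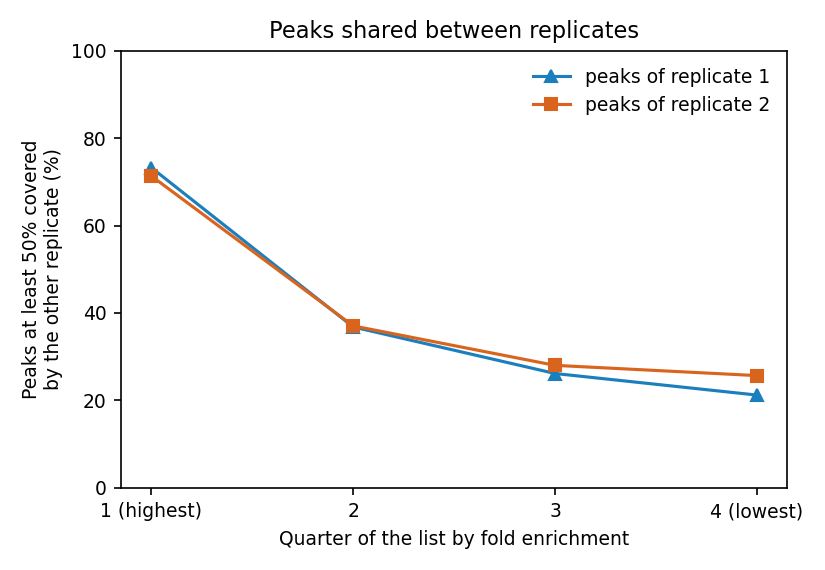
Percent of peaks at least 50% covered by the other replicate (y axis) in 4 equal parts of each replicate's list, ranked from highest to lowest fold enrichment (x axis), with triangles for replicate 1 and squares for replicate 2. The share falls from 73.2% to 21.2% in replicate 1 and from 71.3% to 25.7% in replicate 2.

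All 64356 replicated peaks were identical in position to a pooled peak, and they made up 41.8% of the pooled peaks and 70.9% of their base pairs. Of these, 49.1% had at least 50% of their length covered in both replicates, 21% in replicate 1 only, 22.8% in replicate 2 only and 7.18% in neither. A set of pooled peaks required to have that coverage in both replicates held 31578 peaks. On X, 53.6% of replicated peaks had that coverage in replicate 2 only and 5.83% in replicate 1 only, against 19% and 22.9% on autosomes.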

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

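The restriction to autosomes was chosen after the data were examined, and the other alternatives before. Of 428 alternative values for the comparisons, 372 kept their direction and side of the threshold or their size, and 56 did not. Of the 23 gene lists, 13 kept their call under every alternative they could be given. No olfactory receptor or keratin-associated protein gene had a CpG ratio of at least 0.6, so that setting gave no value for them. The number of lists more marked than other genes stayed between 11 and 14, and that of lists less marked between 3 and 5, except for 1 with CpG-rich genes only, a setting that removes most genes of these families. The shared peaks passed the shift test under all 6 alternatives, from 25.5% with an overlap of at least 80% to 49.6% with 1 bp for replicate 1. The promoter and exon shares did so under all 7. Of 715 alternative calls for 143 named genes, 690 were unchanged, 7 were lost and 18 gained. Most of these genes were named for the most or least coverage, so stable calls are partly built in. Stricter thresholds only remove peaks, so they cannot mark an unmarked gene. The cause of the changes that follow was not tested unless stated. Depth, which the peak lists do not give, limits every count of peaks and unmarked genes.

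Stricter thresholds lowered the covered genome per replicate by construction, to 42.7 Mb with a -log10 q of at least 2 and 33.9 Mb with a fold enrichment of at least 3, and autosomes alone held 49.0 Mb. The X ratio became 2.25 and 2.76 with the same thresholds. A fold enrichment of at least 3 gave a mean Hox promoter coverage of 91.9%, with 77.1% in paralog groups 1 to 4, left 1014 broad domains, and brought clustered protocadherins past the threshold at 7.02%. Joining across 1 kb gave 1059 domains, and the pooled list 3836. The set of pooled peaks with at least 50% of their length covered in both replicates held 31578 peaks. Asking for at least 50% of the promoter window left 2923 marked promoters, and the vascular, blood and microglia list passed at 31.8%.

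Imprinted genes lost their call at 35.7% with windows of 500 bp, 46.4% with 2.5 kb, 39.3% with the q threshold and 42.9% against matched random lists. Cell cycle inhibitors passed at 57.1% with windows of 500 bp, coverage of at least 50% or the fold threshold, 85.7% with 2.5 kb and 71.4% in the pooled list. Housekeeping genes passed as less marked at 3.57% with 500 bp, 10.7% with 2.5 kb or the pooled list, 0% with coverage of at least 50%, and 7.14% against matched random lists. With CpG-rich genes only, pan-neural genes passed at 56.2%, and the vomeronasal list (0%) fell short with 1 gene left. In the same setting pluripotency genes (20%, 1 of 5) lay below and protocadherins (26.7%, 4 of 15) above other genes, both without a call. Keratin-associated protein genes lost their call at 3.51% against matched random lists and 0% with neighbours counted once. The Polycomb machinery, never past the threshold, lay below other genes at 16.7% with windows of 500 bp or the outermost TSS, 12.5% with coverage of at least 50%, 29.2% in the pooled list, 25% in replicate 1's own list and 19% with neighbours counted once. The odds ratio for CpG-rich promoters lost its call at 1.01 with the outermost TSS and 0.953 in the pooled list.

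With each replicate's own list in turn, imprinted genes gave 42.9% to 50%, cell cycle inhibitors 71.4% in both, housekeeping genes 7.14% to 10.7%, the Polycomb machinery 25% in both and the CpG odds ratio 0.993 to 1.04. Mean Hox promoter coverage was 88.2% to 91.0%, with 73.7% to 81.4%, 89.7% to 90.4% and 97.9% to 98.7% in paralog groups 1 to 4, 5 to 8 and 9 to 13. No paired analysis was possible because the series has 1 group.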

Other observations

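The tests of the X chromosome in this part were chosen after its coverage had been seen, and the bound used for the depth explanation was written after the value it judges. Some genes for noncoding RNA also had a peak near their annotated start. Of 5305 lincRNA genes, 721 (13.6%) had a replicated peak within 1 kb of a TSS, and the replicates' own lists gave 18.0 ± 1.11% (SD, n = 2). For 2958 antisense genes these values were 18.9% and 21.6 ± 0.980%, and for 2196 miRNA genes 10.3% and 11.4 ± 0.193%. For miRNA genes the position used was the start of the annotated transcript, which need not be where transcription starts. No difference between kinds of gene was tested. The shares were not set against shifted positions, so they do not show that the mark is enriched at these starts. Of the 2034 broad domains, 953 held no protein-coding TSS.

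On X, 22 of 132 genes with a CpG-rich promoter and no mark in replicate 1 were marked in replicate 2 (16.7%), against 220 of 6009 on autosomes (3.66%). In the reverse direction, 3 of 113 on X (2.65%) were marked in replicate 1 alone, against 3.84% on autosomes. Among ubiquitously expressed X-linked genes, Rps4x, a ribosomal protein gene, gained 419 bp, Hccs, a mitochondrial enzyme gene, 470 bp and Pdha1 of pyruvate metabolism 1 bp. Usp9x went from 480 to 991 bp and Ogt from 357 to 866 bp. These 5 genes were picked after their values were seen. Mid1, which escapes X inactivation in mice, had 941 and 977 bp in its promoter window, and the escape genes Kdm6a, Kdm5c, Eif2s3x, Ddx3x and Pbdc1 had 0 bp there in both replicates. Within 5 kb of a TSS, Mid1 had 2951 bp in replicate 1 and 4779 bp in replicate 2, Kdm5c 1199 and 2175 bp, Ddx3x 84 and 367 bp and Pbdc1 0 and 187 bp, while Kdm6a and Eif2s3x had 0 bp in both. Coverage of the gene body was 14.5% and 32.2% in Mid1 and 6.57% and 15% in Pbdc1.

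Replicate 2 had more of X covered than replicate 1. A deeper or more sensitive library would have raised the autosomes as well, and the X ratio of 2.54 lay above the autosomes' highest ratio of 0.948, which argues against it as the whole cause. An even shift of the X background, as controls with another X dose could give, stays open, since the replicates' lists were derived from different numbers of further files. It was to be excluded if the X base pairs covered in replicate 2 alone fell in promoters more than under every shift, and they did (all 1000 shifts), at 3.57% against a highest value of 2.93%. Their share within genes was also above every shift, at 50.2% against a highest value of 48.7%, but autosomes were not given the same measure. The bound on promoters proved too weak, because base pairs covered in replicate 2 alone on autosomes also exceeded their shifts, at 7.41% against 3.10%, so a higher promoter share does not require a change specific to X. A larger share of cells with an inactive X in replicate 2, for example from more female embryos in the pool, may also account for the pattern, but 3 of 21 ubiquitous genes against 0 of 5 escape genes gained coverage (p = 0.512, one-sided Fisher's exact test), and these few genes cannot tell the explanations apart.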
